A study of Homo sapiens with 2 samples.

How the data were processed

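The series measured gene expression with 1-colour Affymetrix arrays in 2 tumours. GBM43 is a glioblastoma that is propagated by passage in mice (a patient-derived xenograft). Per the labels' protocols, equal amounts of GBM43 tumour were implanted under the skin of immunodeficient nude mice. The mice received 6 doses of the solvent DMSO or 6 doses of panobinostat at 15 mg/kg, given 3 times a week, and tumours were taken at the end of treatment. Total RNA was extracted with a column kit at the same time for both groups and labelled with biotin by the WT Plus kit, again per the labels' protocols. There was 1 array per treatment. The labels do not state whether an array held RNA of 1 tumour or a pool, and below each array is called a tumour.

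The deposited table held log2 expression values of 23786 probe sets on each array. The authors made them with RMA in the affy package 1.36.1 under R 2.15.1, per the submitters' processing notes. RMA subtracts background, equalises the distribution of probe values between arrays and summarises the probes of a set on the log2 scale. Quantile normalization removes any shift shared by all genes, so every difference is relative to the rest of the array. Background subtraction and summarisation compress large differences, more so for dim genes. Which arrays were normalized together is not given in the sources used here. The values ranged from 0.66 to 12.1 in the DMSO tumour and from 0.58 to 12.0 in the panobinostat tumour, with medians of 3.79 and 3.82. The table carried no detection call and no read depth, so the number of arrays limits the precision.

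Probe sets were named by Entrez Gene number, 1 per gene. A platform annotation paired 22458 of them with 1 gene symbol each and none with several. The other 1328 were unnamed here and entered no comparison. XIST and Y-linked genes were left out (41 probe sets), which left 22417 genes. Gene types and neighbours came from RefSeq's table for GRCh38.p14, and no coordinates are given because the sources used here name no build for the array. Genes with a mean over both arrays at or above the 40th percentile (a log2 value of 3.13) were analysed, 13450 in all, of which 12003 are protein-coding. As a guide to background, the 374 olfactory receptor genes on the array, which tumours hardly express, had median values of 1.76 and 1.75, and 95% of them lay below 3.13 in the DMSO tumour and below 3.12 in the panobinostat tumour. This guide was added after the data were seen, and so were the lower bounds of folds, in which a value below the guide is set to the guide.

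The difference per gene was the panobinostat value minus the DMSO value on the log2 scale, and folds are 2 to the power of that difference. With 1 array per treatment there was no test between treatments, no replicate check and no p-value. Counts used a 2-fold threshold. For 43 gene lists, fixed before the data were examined, the median difference of the members above the filter was set against the medians of 10000 random lists of the same size, matched on mean expression in 20 bins. A list is said to stand apart when its median lay outside the central 95% of the random lists, which describes these 2 arrays only. Members of real lists vary together more than randomly drawn genes do, so the random range is narrower than the range that unrelated tumours would give. Lists with under 3 members above the filter were not set against random lists, a minimum chosen after the data were seen. The lists named 741 different genes, of which 681 were measured, 3 of them under a newer symbol, and 559 passed the filter.

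Most genes named were taken by a rule fixed before the data were examined. Exceptions, chosen after their values were seen, are the members of gene families in the closing observations. The rule holds the 14 highest and the 14 lowest protein-coding genes above the filter, the 2 highest and 2 lowest members of each list, and 11 genes fixed by name, of which 2 are not reported here. Genes with near-identical copies (histones, metallothioneins, HLA genes, the PRAME family, gamma protocadherins, HMGN2, ASAH2 and a few others) can share probes with their copies, and their values are uncertain.

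The alternatives fixed before the data were examined were no brightness filter, a filter at the 60th percentile, removal of a running median over 501 genes along mean expression, removal of the overall median, thresholds of 1.5-fold, 3-fold and 3 spreads of like genes, random lists that were unmatched or matched on the DMSO value, lists without shared members, and means in place of medians. The procedure was tested on simulated data made by shuffling the 13450 differences of panobinostat against DMSO among genes of like brightness. Of 160 unshifted lists, 3.75% were called apart. A low share follows from the shuffling, which removes the way members of real lists vary together. It is no estimate of false calls among real lists. A simulated shift of 0.2 was found in 68.1% of lists and one of 0.3 in 90.6%. The lists drawn held at least 10 members above the filter and were set against fewer random lists. These rates therefore do not hold for shorter lists, whose random range is wider. Of 200 genes changed by 1.5 on the log2 scale, 95.5% passed the 2-fold threshold, but of 200 changed by 1 only 47.5% did. In the same simulation 134 unchanged genes passed it. Shuffling keeps the large differences of the data, so this count is no rate of false calls. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.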

Results

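The data compare the transcriptome of a GBM43 glioblastoma xenograft from mice given panobinostat, an inhibitor of histone deacetylases that blocks the removal of acetyl groups from histones and other proteins, with that of a xenograft from mice given the solvent DMSO. Each treatment had 1 array. The question was which genes differ in expression between the treated and the control tumour. All values are RMA-normalized log2 values, differences are panobinostat minus DMSO, and there are no replicates, so no value carries an error and no p-value is given.

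The tumours were closely alike, and few genes differed by 2-fold or more. Across the 13450 genes above the brightness filter the values of both tumours correlated with r = 0.977, a correlation over genes, which are not independent replicates. The differences had a median of 0 and an SD of 0.33, and 92.8% of genes differed by less than 1.5-fold. At least 2-fold higher in the panobinostat tumour were 77 genes and at least 2-fold lower were 58, together 135. The share of such genes was 1.07% among the 374 olfactory receptor genes (4 genes), which lay near background in both tumours and whose 95th percentile (3.13 with DMSO, 3.12 with panobinostat) serves as a background guide. Most of the 135 genes were dim: 77 were in the dimmest of 3 equal parts by brightness, 45 in the middle part and 13 in the brightest, where the SD was 0.27. Of the 135, 57.0% were higher with panobinostat (Wilson 95% interval 48.6% to 65.1%, counting error only).

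Among the 14 protein-coding genes that stood highest above the control, VSNL1, a neuronal calcium sensor, was at 5.70 in the DMSO tumour and at 7.70 in the panobinostat tumour, 3.99-fold higher. MAPRE3, a microtubule end-binding protein abundant in neurons, was 3.57-fold higher, SERPINI1 (neuroserpin) 2.85-fold and CALB1 (the calcium buffer calbindin) 2.64-fold. CHRM4, a muscarinic acetylcholine receptor, was at 2.94 in the DMSO tumour, below the background guide, and at least 2.31-fold higher when measured from the guide. TXNIP, which restrains glucose uptake and thioredoxin, was at 5.86 and 7.47, 3.06-fold higher. PDK4, the kinase that shuts off pyruvate dehydrogenase, was 3.00-fold higher and GLRX (glutaredoxin) 3.26-fold. The others among the 14 highest protein-coding genes were MMP1, an interstitial collagenase, at 2.83-fold, the homeobox gene MSX2 at 2.67-fold, ARRB1 (beta-arrestin) at 2.61-fold, CRYBG1 at 2.91-fold and PCDHGB1 at 3.11-fold. SERPINI1 (3.16), MMP1 (3.20) and MSX2 (3.22) lay close to the background guide in the DMSO tumour, and their ranks are uncertain. PRAMEF25 was at 2.40 in the DMSO tumour, below the guide, and at 4.50 in the panobinostat tumour, at least 2.59-fold higher from the guide. PCDHGB1 shares exons with other gamma protocadherins and PRAMEF25 has near-identical copies, so their identity is uncertain.

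The lowest difference was that of ANGPT2, an angiopoietin that destabilises blood vessels, at 5.23 in the DMSO tumour and 3.17 in the panobinostat tumour, 4.17-fold lower and in the latter close to the background guide, so that its rank is uncertain. GABBR2, a subunit of the GABA-B receptor and the brightest of this group, was at 8.05 and 6.18, 3.67-fold lower. NAV3, a neuron navigator, was 2.94-fold lower, DLK1, a non-canonical Notch ligand, 2.68-fold, GATA2, a transcription factor of blood and endothelial lineages, 2.46-fold, and HMOX1 (heme oxygenase 1) 2.43-fold. HS6ST1, a heparan sulfate sulfotransferase, was 2.56-fold lower, N4BP2 2.42-fold and LOC647264 2.35-fold. The others of the 14 lowest were below the guide in the panobinostat tumour, and their folds down to the guide are lower bounds: 2.27-fold for the splicing factor gene ZRSR2, 1.58-fold for the death adaptor CRADD, 2.61-fold for HMGN2, 2.67-fold for the histone gene H2BC9 and 1.79-fold for ASAH2. HMGN2, H2BC9 and ASAH2 also have near-identical copies or pseudogenes.

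**Figure D1:**
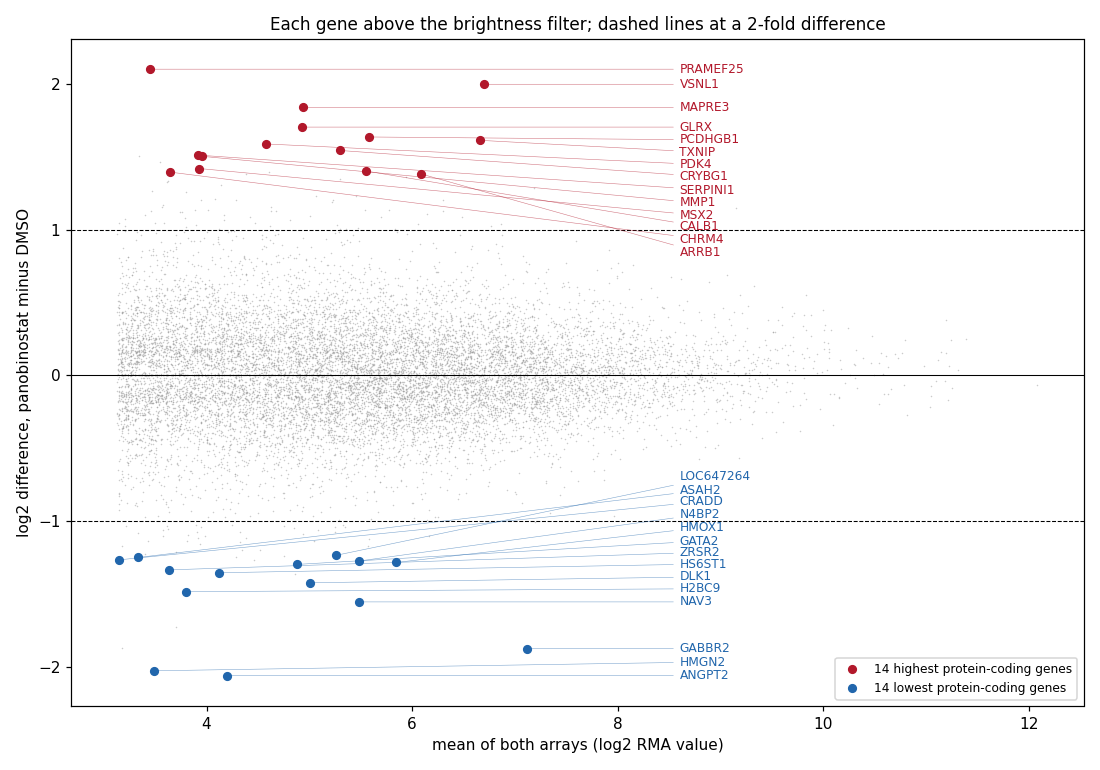
Log2 difference (panobinostat minus DMSO, 1 array each) of every gene above the brightness filter against its mean log2 value over both arrays. Red and blue points are the 14 highest and 14 lowest protein-coding genes, plotted at their RMA values, also where 1 value lies below the background guide (PRAMEF25, CHRM4, ZRSR2, CRADD, HMGN2, H2BC9 and ASAH2). MAPRE3 stands at 1.84 and ANGPT2 at -2.06, and the cloud narrows toward bright genes.

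Genes usually raised by histone deacetylase inhibitors did not stand apart as a group. Of the 17 measured above the filter, 9 were higher and 8 lower, with a median difference of 0.02 at the 52.8th percentile of random lists. The sign depended on the setting, with a median of -0.05 without the brightness filter and -0.10 without genes of other lists, and a mean of 0.14, each inside the random range. TXNIP (1.61) and TP53INP1, a p53-induced stress protein (3.62 in the DMSO and 4.63 in the panobinostat tumour), were the highest, and H2BC21 (-0.44) and KLF4 (-0.36) the lowest. CDKN1A, which encodes the cell cycle inhibitor p21, was at 3.73 in the DMSO tumour and 3.76 in the panobinostat tumour. The 11 classical histone deacetylases, which include the targets of the drug, had a median of 0.07 (73.3rd percentile), with HDAC1 at 0.27, HDAC2 at 0.10, HDAC3 at 0.01 and HDAC6 at 0.00. HDAC9 was the highest (0.35) and HDAC10 the lowest (-0.44).

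Genes of cell division were lower in the panobinostat tumour by a small amount, with few exceptions. Of 24 mitosis genes 22 were lower, with a median difference of -0.27 (83.1% of the DMSO level), below each of the 10000 random lists. PLK1, the mitotic polo-like kinase, was at -0.72, CCNB1 (cyclin B1) at -0.65 and the proliferation marker MKI67 at -0.45, while CDK1 (0.16) and AURKA (0.05) were not lower. Of 27 DNA replication genes 25 were lower, with a median of -0.22 (0.04th percentile). The replication licensing factor CDT1 (-0.61) and the origin recognition subunit ORC1 (-0.59) were the lowest, and CCNE1 (cyclin E1) was the highest (0.37). Replication-dependent histone genes had a median of -0.22 (0.24th percentile), with 9 of 14 lower, H3C1 at -1.06 and H2BC14 at 0.58. The lowest was H2BC9, at least 2.67-fold lower, as given above. Without the brightness filter their median was 0.00 over 21 genes, inside the random range. Genes of homologous recombination and Fanconi repair were lower in 10 of 12 cases, with BRCA1 at -0.69 and CHEK1 at -0.45, but their median of -0.17 lay inside the random range (5.75th percentile). Skeletal muscle markers, given below, were lower in the same tumour, with a median of -0.40.

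Sterol and ribosome synthesis genes were lower as well. Of 16 genes of cholesterol synthesis and its control, 11 were lower, with a median of -0.23 (0.26th percentile). FDPS (farnesyl diphosphate synthase) was at 3.89 in the DMSO tumour and below the background guide in the panobinostat tumour (2.91). DHCR7, which catalyses the last step of cholesterol synthesis, was at -0.88. STARD4, a sterol carrier, was the highest at 0.29. In the list of MYC and ribosome biogenesis genes 13 of 18 were lower, with a median of -0.17 (0.73rd percentile), led by RRS1 (-0.68) and NOP2 (-0.57), which act in ribosome assembly. MYC itself was the highest member, at 0.18. These lists were lower in the same tumour as the skeletal muscle markers (-0.40). Ribosomal protein genes did not share this direction: 13 of 17 were higher, with a median of 0.10 inside the random range (87.6th percentile), RPS23 being the highest (0.32) and RPS14 the lowest (-0.17).

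Hypoxia genes were higher in the panobinostat tumour in 18 of 18 cases. Their median difference was 0.29 (1.22-fold), above each of the 10000 random lists. The largest differences were those of STC2, a secreted glycoprotein (0.81), and EGLN3, an oxygen-sensing prolyl hydroxylase (0.56), and the smallest those of PFKFB4 and ANKRD37 (both 0.03). Glycolysis genes had a median of 0.10 (87.8th percentile), with the glucose transporter SLC2A3 at 0.88 and LDHA at 0.47, and with HK2 at -0.42 and TPI1 at -0.30. Fatty acid oxidation genes were higher in 15 of 18 cases, with a median of 0.17 (99.2nd percentile). HADHB and DECR1, enzymes of mitochondrial beta-oxidation, were at 0.49 and 0.48, and ACAD9 was the lowest at -0.11. Oxidative phosphorylation genes were inside the random range (median 0.03, 65.8th percentile), from SDHC at -0.27 to UQCRC2 at 0.37.

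Metallothioneins, small metal-binding proteins, were higher in 6 of 7 cases above the filter, with a median of 0.49 (1.41-fold), above each of the 10000 random lists. MT1X was at 0.71 and MT2A at 0.61, and MT1M at -0.01. Without the brightness filter the median of 9 was 0.25 (99.4th percentile). Their sequences are alike, so the members are not independent readings. Autophagy and lysosome genes were higher in 13 of 19 cases, with a median of 0.23 (99.7th percentile). WIPI1 (0.82) and MAP1LC3B (0.54), which act in autophagosome formation, were the highest, and HEXA (-0.33) and ATG7 (-0.27) the lowest.

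Neuronal and mesenchymal genes were both higher. Of 15 neuronal genes above the filter 12 were higher, with a median of 0.34 (1.27-fold, 99.99th percentile). STMN2, a regulator of axonal microtubules, was at 0.82 and the neuronal RNA-binding protein gene ELAVL3 at 0.74, and DCX (-0.15) and INA (-0.11) were lower. Over all 22 measured members the median was 0.21 (99.5th percentile), but the members added lay below the background guide in both tumours. Of 20 mesenchymal glioblastoma genes 18 were higher, with a median of 0.25 (1.19-fold, 99.98th percentile), among them the urokinase receptor gene PLAUR (0.61) and the inflammatory caspase CASP4 (0.54), while RELB (-0.22) and IL1R1 (-0.12) were lower. Proneural genes (median 0.16, 93.2nd percentile) went both ways, with PDGFRA at 0.76 and CHD7 at -0.44. Without the brightness filter their median was 0.04, and over the 5 above the 60th percentile it turned to -0.17. Among glioma stem and progenitor genes (median 0.13, 94.7th percentile) the integrin ITGA6 (0.85) and ID1 (0.66) were highest, and SOX2 (-0.57) and MSI1 (-0.42) lowest. Astrocyte genes had a median of 0.04 (60.6th percentile), with S100B at 0.68 and GFAP at 0.63 against SLC1A2 at -0.45. The 4 oligodendrocyte genes above the filter had a median of 0.20 (86.0th percentile), led by CLDN11 (0.85), with CNP at -0.32. Over all 12 measured it was 0.00, and over the 3 that belong to no other list -0.02. Cadherins and regulators of the epithelial-mesenchymal transition had a median of 0.20 (96.8th percentile), from TWIST1 at -0.40 to KRT8 at 0.42.

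Antigen presentation genes were higher in 10 of 15 cases, with a median of 0.24 (99.1st percentile). The class I genes HLA-B (0.71) and HLA-E (0.68) were highest, and CD74, the class II invariant chain, was lowest (-0.73). Without the HLA genes, which can share probes, the median of the other 9 was 0.00, and the median of all measured members without the brightness filter was 0.10, both inside the random range. Interferon response genes had a median of 0.07 (69.1st percentile), from MX1 at -0.60 to IFI44 at 0.71, but -0.02 over all 20 measured and -0.14 over the 5 above the 60th percentile. The NF-kB and cytokine list had a median of -0.02 (36.1st percentile), but 0.09 over all 19 measured, both inside the random range. TNFAIP3 was highest (0.59). CXCL2 was lowest, at 3.56 in the DMSO tumour and below the background guide in the panobinostat tumour (2.74). All 6 NKG2D ligand and checkpoint genes above the filter were higher, from 0.01 (CD276) to 0.50 (MICB), with a median of 0.23 that lay inside the wide random range of so short a list (94.7th percentile). Over all 14 measured it was 0.07, and over the 5 above the 60th percentile 0.08.

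Lists of stress, death and signalling genes did not stand apart. The medians were 0.03 for p53 targets (64.1st percentile), -0.03 for the BCL2 family (37.1st), -0.12 for the ATF4 response (4.74th), 0.02 for endoplasmic reticulum chaperones (51.4th), -0.01 for heat shock genes (36.5th), 0.15 for NRF2 targets (94.5th), 0.05 for ERK pathway output (70th) and 0.03 for receptor tyrosine kinases (58.8th). Some of these values depended on the setting, each staying inside the random range. The p53 median was -0.11 without genes of other lists, and the ATF4 median was -0.02 above the 60th percentile. The mean of the NRF2 targets was 0.003 (43.2nd percentile). Single members lay far from the list medians. PMAIP1, which encodes the pro-apoptotic protein NOXA, was at 0.83 and BAX at 0.34, against HRK at -0.48 and BAK1 at -0.39. Among p53 targets TP53INP1, given above, and CCNG1 (0.52) were highest and AEN (-0.64) lowest. SESN2 was at 0.70 and CEBPG at -0.55 in the ATF4 list, and DNAJB1 at -0.45 and HSPH1 at 0.36 among heat shock genes. EDEM1 was at 0.31 among the chaperone genes, and DUSP4 (0.52) and CCND1 (-0.42) bounded the ERK list. HMOX1 (-1.28) and NQO1 (-0.56), both NRF2 targets, were low while GCLC was at 0.42. Among the receptors KDR was at 1.14, PDGFRA at 0.76, ERBB2 at -0.59 and EGFR at 0.02. MGMT, the repair gene for alkylated guanine, lay near background in both tumours (2.65 and 3.17).

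Markers of other cell types, which in a xenograft come from the mouse, did not stand apart, except for those of muscle. Human probes can read them by cross-hybridisation or from tumour cells that express them. The fibroblast and mural markers were bright, with a median DMSO value of 6.92, against 3.98 for the endothelial ones. The median differences were 0.05 for 13 fibroblast and mural genes (67.5th percentile), 0.00 for 9 endothelial genes (42.8th), 0.07 for 4 leukocyte and macrophage genes (60.9th) and 0.03 for 3 adipocyte genes (50.0th). POSTN (0.55) and DCN (-0.44) bounded the fibroblast list. Among endothelial markers KDR, which is also in the receptor list, was highest (1.14) and EMCN lowest (3.57, and 2.90 with panobinostat, below the guide), and CD68 was at 0.61 and CFD at 0.31. Skeletal muscle genes stood apart: 6 of 8 were lower in the panobinostat tumour, with a median of -0.40 (0.11th percentile), and the median of all 14 measured was -0.25. The fast troponin TNNC2 was at 3.87 in the DMSO tumour and below the guide in the panobinostat tumour (2.79), and the muscle creatine kinase CKM had a difference of -0.93. KRT14 was the only keratinocyte marker above the filter, at -1.13, and HBA1 (0.42) and HBA2 (0.06) the only erythrocyte markers. Immediate early genes, which respond to handling, had a median of -0.12 (11.1th percentile), with FOSB highest (0.25) and ATF3 lowest, at 3.49 and at the guide with panobinostat (3.12). Reference genes had a median of -0.03 (39.7th percentile) and a mean of 0.01 (53.8th), from POLR2A at -0.32 to HPRT1 at 0.21.

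**Figure D2:**
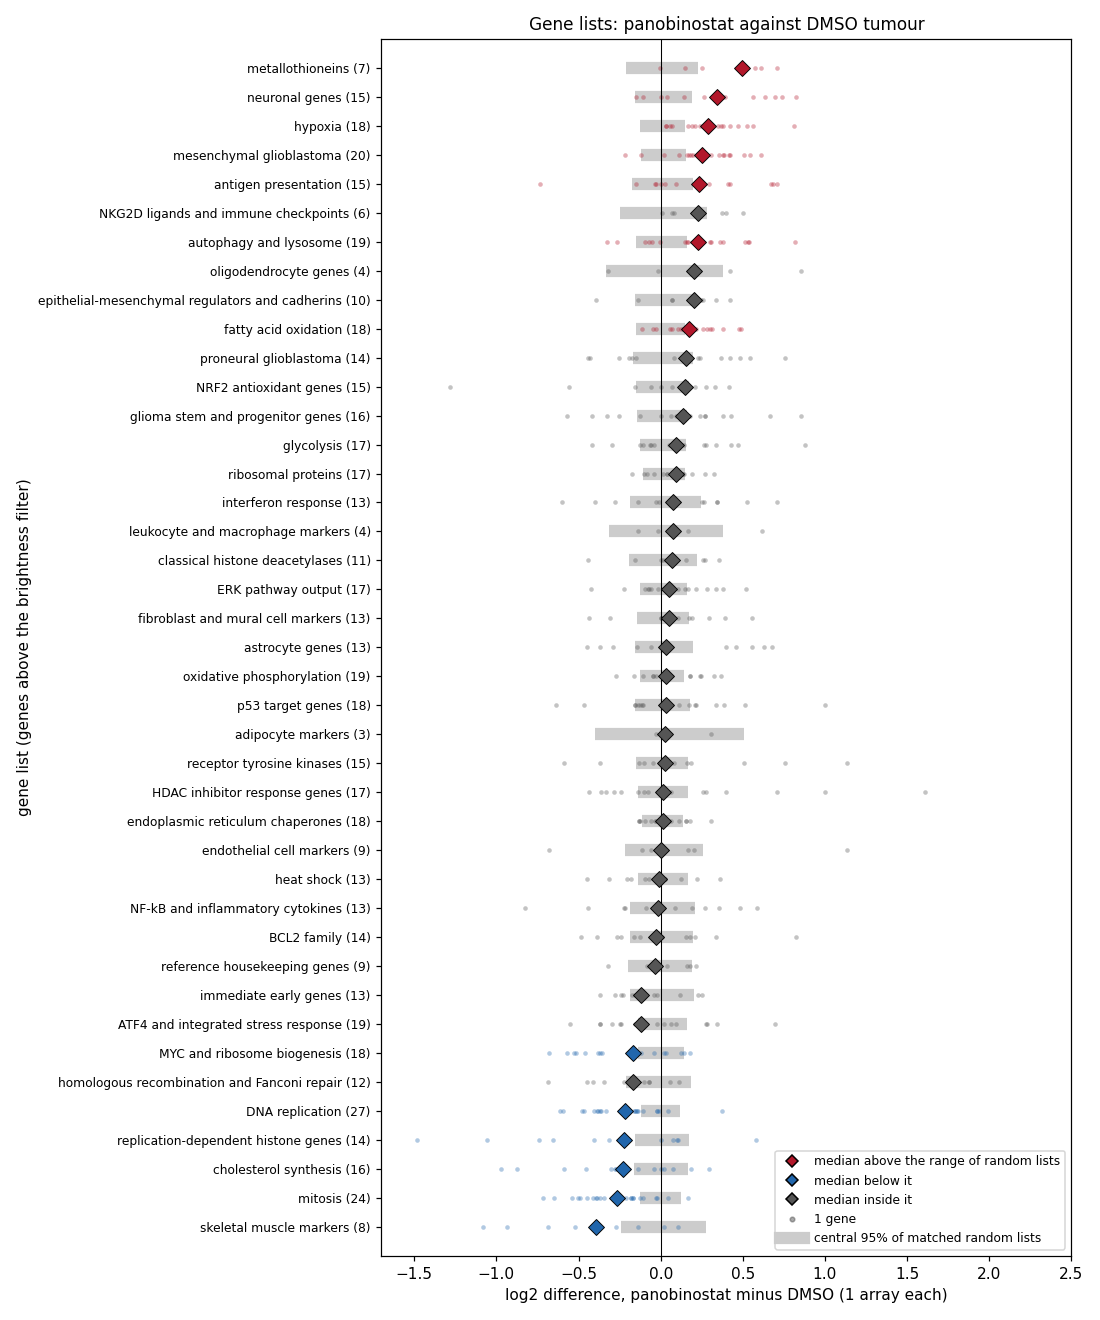
Log2 difference (panobinostat minus DMSO, 1 array each) for the members and the median of each of the 41 lists with 3 or more genes above the filter. Diamonds are list medians, small points single genes and grey bars the central 95% of matched random lists; 7 medians lie above their bar, metallothioneins farthest at 0.49, and 6 lie below, skeletal muscle markers farthest at -0.40.

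Of these 41 lists 13 stood apart, 7 above and 6 below, where about 2.05 would by chance if lists were independent. Lists share members and their genes vary together, and with 1 array per treatment a difference between the treatments and a difference between any pair of tumours cannot be separated.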

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

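The probe sets that had no gene name here entered no comparison, and they were looked at for signal above the control tumour. Of 662 above the brightness filter, 3 were at least 2-fold higher in the panobinostat tumour and 5 at least 2-fold lower, together 1.21%, while 135 of 13450 named genes were. Their differences ran from -1.40 to 1.23 with an SD of 0.33. No group held enough arrays to look for an outlying one, and with a single contrast no effect could be compared between groups.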

How the results depend on the processing

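The number of genes at 2-fold or more (135) depended on the threshold and the brightness filter. It was 203 with no filter, 58 above the 60th percentile, 964 at 1.5-fold, 12 at 3-fold and 210 at 3 spreads of genes of like brightness. The share that was higher with panobinostat stayed between 52.7% and 60.3%. Of 327 list comparisons under the alternatives, 319 kept the list's place inside or outside the random range and none changed it to the opposite side. Part of this count could hardly differ. The overall median was 0, so its removal changed nothing. Random lists that were unmatched or matched on the DMSO value left the list medians as they were. Leaving out shared members did the same for lists that had none. Of the 13 lists that stood apart, 11 did so under every alternative that left 3 or more members. The exceptions were replication-dependent histones without the filter (0.00) and antigen presentation without the filter (0.10) or without genes that have near-identical copies (0.00), a setting chosen after the data were seen. Some lists inside the range moved outside it: epithelial-mesenchymal regulators without the filter (0.20) and with matching on the DMSO value (0.20), stem and progenitor genes (0.21) and astrocyte genes (0.22) above the 60th percentile, and homologous recombination by its mean (-0.21). The cause was not tested. Removal of the running median moved the 36 genes above the filter that the rule names singly by at most 0.054 (ASAH2). The brightest probe set per gene was not run, as each gene had 1. Leaving out a replicate was impossible, and no paired analysis was possible because each treatment had 1 array. Above the 60th percentile, muscle, endothelial, leukocyte, adipocyte and oligodendrocyte markers were too few for a value. Dim genes limit the precision, since their differences spread more widely (SD 0.37 in the dimmest part, 0.27 in the brightest).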

Other observations

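Gene families defined by a shared symbol stem, taken up after the data were seen, showed further groups, though some overlap the fixed lists. Of 147 families with at least 10 genes above the filter, 8 stood above and 15 below the central 95% of matched random lists. About 7.35 would by chance if families and their genes were independent. Genes of a family can vary together or share probes, as members of the lists can. Semaphorins, guidance molecules of axons and vessels, were higher in 12 of 17 cases with a median of 0.39, above each of the 10000 random lists. SEMA4G (0.94), SEMA3C (0.92) and SEMA4F (0.90) were the highest and SEMA6D (-0.76) was the lowest. Genes with the stem ST, many of them sialyltransferases, had a median of 0.31 (99.9th percentile), with ST8SIA4 at 1.01 and ST6GALNAC2 at 0.84. Genes with the stem RPS were higher in 18 of 25 cases with a median of 0.14 (98.3rd percentile). Small-subunit ribosomal proteins share this stem with some kinases, so the value is not one of ribosomal proteins alone. Genes with the stem RPL (0.06 over 37 genes, 81.9th) lay inside the range, as did the fixed ribosomal protein list.

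Among the families below the random range were H/ACA box small nucleolar RNAs (SNORA), which guide pseudouridylation. They were lower in 50 of 70 cases with a median of -0.24, below each of the 10000 random lists, and SNORA50C was at -1.04. The C/D box family did not stand apart (79 higher, 84 lower, median -0.02). All 235 small nucleolar RNA genes above the filter together had a median of -0.10, below the random range. Also below were the METTL methyltransferases with a median of -0.31 over 19 genes, METTL1 being at -0.95, the RBM proteins with -0.21 over 31, the SRSF splicing factors with -0.21 over 12, the TRMT family with -0.26 over 14 and the DDX helicases with -0.15 over 30. Other families that handle RNA lay inside the range, among them EXOSC (-0.17, 4.38th percentile), DHX (-0.14, 4.53rd) and LSM (28.4th). Families without such a role were below it as well, such as the replicative helicase genes MCM (-0.28), COQ (-0.28) and TRIM (-0.13). Several MCM genes are also in the DNA replication list. No theme over families was tested.

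Apart from the test of whether glycolysis genes carry the hypoxia list, the tests below were chosen after the results they concern had been seen. The brightness-dependent difference between the arrays was small, with a running median of at most 0.077 in size. The lower level of cell division genes (51 genes of both lists, median -0.22) exceeded it. After the running median was taken off the median was still -0.22, outside the random range of -0.09 to 0.08. A removal of that size could not have changed the call, so this outcome adds nothing to the size of the running median. A smaller share of tumour cells would lower other glioma genes alike. Quantile normalization removes a shift shared by most genes, so the level of these genes cannot decide on that share. The stem, progenitor and proneural genes had a median of 0.18 (bootstrap 95% interval over 29 genes -0.13 to 0.27). So did the 17 above the 60th percentile (-0.19 to 0.38), though their 5 proneural members alone had -0.17. The cell division genes were thus low relative to this set of glioma genes, and the share of tumour cells stays open. A difference between single tumours unrelated to the treatment cannot be told apart from an effect of panobinostat, because there was 1 array per treatment. A treatment effect stays open on the same ground.

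The higher hypoxia genes did not rest on the 2 genes shared with the glycolysis list. Without them the median of 16 genes was 0.28, at the 99.97th percentile. Dropping 2 genes could not have changed the call, so the test carries little weight. Of the hypoxia genes 18 of 18 were higher, with a lower quartile of 0.17. These are the same values that made the list stand apart, so they add no separate support. A longer time before RNA was taken would raise immediate early genes, and these had a median of -0.12 (bootstrap 95% interval over 13 genes -0.23 to -0.02). As that median lay inside the random range (11.1th percentile), such a delay stays open. Tumour size and perfusion were not measured here and stay open, as does the treatment.

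A hypothesis is that the lower skeletal muscle genes come from muscle carried along with the DMSO tumour, which was implanted under the skin. Of all 14 measured markers, dim ones included, 78.6% (11) were lower with panobinostat, short of the 80% set for a clear answer, so this stays open. Their median of -0.25 was below the random range (0.32nd percentile). More mouse tissue of every kind in the DMSO tumour stays open too: dim markers of the other cell types had a median of 0.00 (14 genes) and dim muscle markers one of -0.52 (7 genes), but the bootstrap 95% interval of the difference, -0.04 to 1.03, included 0.

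Exactly equal values on both arrays were found for 1596 of 23786 probe sets (6.71%), with a median level of 2.16. Of the genes above the filter 24.4% had a difference of exactly the same size as another gene, against 9.63% (13) of the 2-fold genes and none of the 28 highest and lowest genes. Differences of neighbouring genes on the autosomes correlated weakly (r = 0.050 over 13019 pairs, a correlation across genes), above the highest of 1000 shuffles (0.032). The cause of this correlation, which may include probes shared between near-identical copies, was not tested.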
